A study of Mus musculus with 34 samples.

How the data were processed

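Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts and tags open DNA, in mouse embryonic fibroblasts (MEF) and embryoid bodies (EB, aggregates of differentiating embryonic stem cells). The labels describe 34 samples in 17 groups of 2. The cells carry a doxycycline-inducible Etv2, an ETS-family transcription factor of the blood and vessel lineages. Brg1, the ATPase subunit of the SWI/SNF chromatin remodelling complex encoded by Smarca4, was knocked down in a set of MEF groups. In a set of EB groups Brg1 was floxed and the cells were or were not given 4-hydroxytamoxifen (4OHT).

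Reads were aligned with Bowtie2 2.2.4 to the mm10 mouse genome and peaks were called with MACS2, and HOMER was also used, per the submitters' processing notes. No label records read trimming, the handling of duplicate or mitochondrial reads, the shift for transposase cutting or a blacklist. The files used here hold summits, the single base of highest signal in a peak or in a part of it. The deposited score of each summit is the −log10 of the peak caller's q value. All 19 lists have every score above 1.30, which is a q value of 0.05. Such a score grows with sequencing depth, so no score was compared between lists summit by summit. A fixed score limit, used in an alternative and for the removed bins, takes a different share of each list. Read depth per sample was not analysed here. The number of summits in a list is the only stand-in for depth used, and it need not follow depth. Signal tracks were not used here.

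For 15 groups (30 samples) the labels of both replicates name the same summit list, so these lists hold 1 value per group, and their comparisons carry no replicate error and no p-value. Exact Clopper-Pearson 95% intervals are given for shares and cover counting error only. How the replicates were combined is not recorded in the labels. The 4 floxed EB samples have a list each.

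The written form of the scores shows that the lists were not all processed alike. Between 27.6% and 55.9% of scores in the MEF lists without knockdown and in the 3 EB lists from 12 h have more than 6 significant digits, against 0 in the knockdown and floxed lists. The floxed lists hold at most 1 summit per peak, whereas the knockdown lists hold up to 190. A comparison of knockdown with no knockdown therefore cannot be told apart from a difference in processing. Lists with and without doxycycline share the written form of their scores, which does not prove that they were processed together.

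Analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Summits on chromosomes 1 to 19 and X were kept. A summit was shared between lists when the other list had a summit within 250 bp. A summit of the induced list with no such partner was called gained, and a summit of the control list with none was called lost. These words describe list membership and not a tested change. Genes came from a reference table of the GRCm38.p6 assembly (mm10), and all 290 gene symbols of 13 gene lists were found among its 21631 protein-coding genes. That table has no strand, so a transcription start could not be placed. Summits were instead counted within 50 kb of the gene interval, and a summit within 1 kb of either gene end was called a gene-end summit. The plan had named the transcription start for both.

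The design, the gene lists and the rule for named genes were set before the data were examined. For each list and comparison, gained minus lost summits were counted per gene, and the list's median was ranked among 10000 random gene lists of the same size. Genes were ranked by the number of summits around them in both lists together, with ties in order of symbol. Each random gene was drawn from within 100 ranks on either side of a list gene, which could be drawn itself. A list stands apart when its percentile lies below 2.5 or above 97.5. Ties with random lists are split evenly, and medians of small counts can tie. A middle percentile can therefore hide a shift, and the mean was ranked in the main setting only. This covers 195 pairs of a list and a comparison, and the percentiles describe these libraries without testing the conditions. The lists were endothelial (50 genes), haematopoietic (22), fibroblast (48), pluripotency (25), mesoderm (25), cardiac (19), endoderm (14), neural (20), skeletal muscle (12), macrophage (12), epithelial (12), SWI/SNF (18) and housekeeping (20). The genes that may be named are, per comparison and list, the 5 with the highest and the 3 with the lowest gained minus lost counts, for the endothelial, haematopoietic and fibroblast lists in MEF and the endothelial, haematopoietic, pluripotency, mesoderm and cardiac lists in EB. To these come the nearest genes of the 5 highest-scoring gained and the 5 highest-scoring lost summits, and Etv2, Kdr, Smarca4, Gapdh and Actb in every list. The text gives examples from this set.

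Induced MEF lists of all days share 1 uninduced control list. To show what that alone gives, unchanged lists were simulated 100 times from the recurrence of each region in the 5 uninduced MEF lists, at the observed list lengths. All but 1 of these lists are knockdown lists, which were processed differently, so the simulated values are a rough guide for lists without knockdown. The floxed EB lists were compared 2 against 2 by an exact two-sided permutation test of group means, with a sign-flip test on replicate numbers as an alternative. Matching and the gene-list step were tested on simulated data made from the uninduced EB list over 21631 genes. The simulated gained summits were placed away from every summit of that list, so finding 100% of them was fixed beforehand. The simulated lost summits were found in 96.6% of cases. The endothelial list moved from percentile 54.7 with nothing added to 99.96 with 1 summit added per gene. Of 200 random lists 2% fell outside the limits by the median and 5.5% by the mean.

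Alternatives tried were matching within 100 bp or 500 bp, a score of at least 10, the same number of highest-scoring summits from each list, a gene window of 10 kb, every chromosome, leaving out each floxed sample and the replicate block. Added after the data were seen were the mean in place of the median, and removal of 24 bins of 10 kb where all 15 pooled lists have a summit scoring at least 200. The neighbouring bin on each side was removed with them. The share of regions called with doxycycline alone was also added then. Every motif result that had been planned, for ETS and AP-1 sites, was left out because it needs the genome sequence, which was not used here.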

Results

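Open chromatin was mapped by ATAC-seq while Etv2, a transcription factor that specifies endothelial and blood progenitors, was induced with doxycycline in mouse fibroblasts and in embryoid bodies. The 34 samples form 17 groups of 2. MEF without knockdown were profiled uninduced (day 0) and on days 1, 2 and 7 of induction, the last both unsorted and as cells positive for Flk1, the receptor that Kdr encodes and that marks early endothelial and blood progenitors. MEF with Brg1 knockdown were profiled on day 0 and, with and without doxycycline, on days 1, 2 and 7. EB were profiled 12 h after induction per their labels, uninduced, induced, and induced and sorted for Flk1. Brg1-floxed EB were profiled on day 4, with doxycycline per the labels, with or without 4OHT, a drug commonly used to switch on a tamoxifen-dependent recombinase. The series design text describes the latter as Brg1 knockout, and it also names EB at 3 h, which were not analysed here. The pooled lists have no replicates, so their comparisons are differences between lists.

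The number of accessible positions called varied widely. The uninduced MEF list held 62028 summits, and the induced lists held 50015 on day 1, 26217 on day 2 and 18418 on day 7, with 29520 in the Flk1-positive cells. Knockdown MEF ranged from 11188 summits (day 7 without doxycycline) to 44493 (day 2 without doxycycline). The EB lists held 85498 summits uninduced, 77987 induced and 58004 in induced Flk1-positive cells. Shorter lists lay closer to genes. Of uninduced MEF summits 23.8% (95% exact interval 23.5 to 24.2%) were at a gene end, against 44.0% (43.3 to 44.7%) in induced MEF on day 7. Gene ends shifted by 300 kb gave between 3.67% and 5.02% across all 19 lists. Both day-7 knockdown lists departed from this, with 29.1% and 27.4% at gene ends despite being the shortest.

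**Figure D1:**
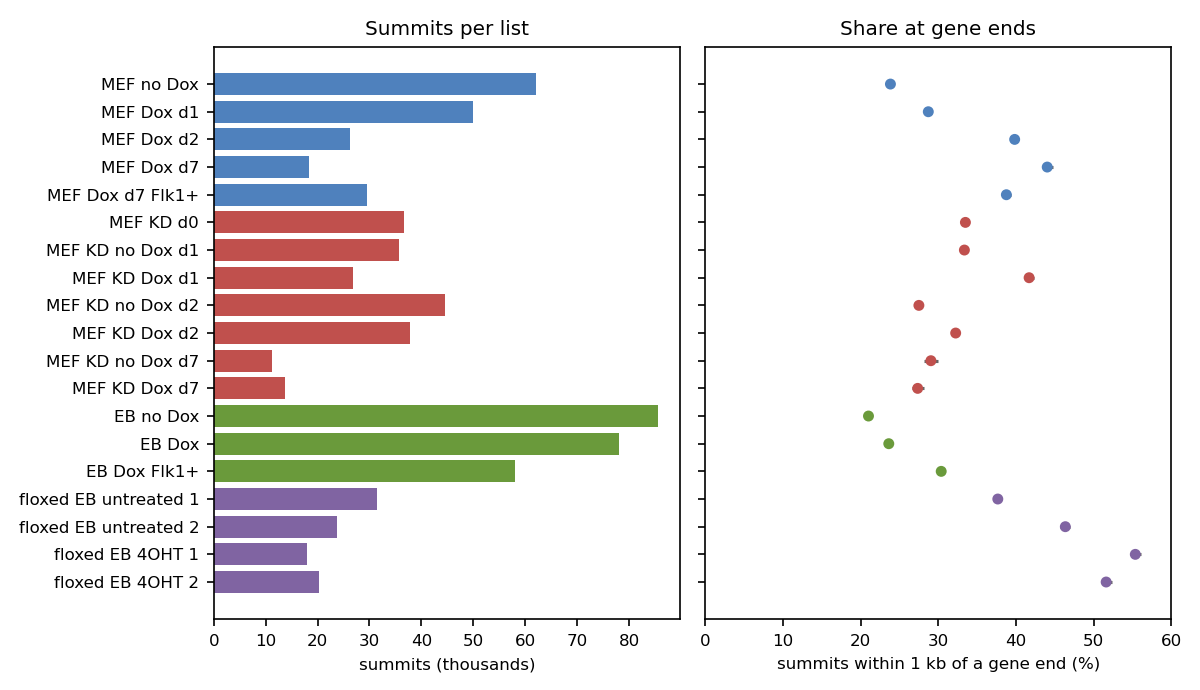
Number of summits per list (bars, left) and the percent of them within 1 kb of a gene end (points with exact 95% intervals, right) for the 15 pooled lists and the 4 floxed EB samples, coloured by MEF, knockdown MEF, EB and floxed EB. List length ran from 11188 to 85498 summits, and the gene-end share from 21.0% in uninduced EB to 55.4% in a 4OHT sample.

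Smarca4, the gene for Brg1 on chromosome 9 (21616106 to 21704230), had 7 summits within 50 kb in uninduced MEF and 5 in knockdown MEF on day 0. A knockdown acts on the RNA, so these counts do not check its level. In the floxed EB it had 5 and 4 summits without 4OHT and 3 and 3 with it, and summits do not resolve a deleted exon. Gapdh, a glycolytic enzyme gene used as a reference, had 7 to 10 summits in the MEF lists without knockdown and 2 and 6 in the day-7 knockdown lists without and with doxycycline. Actb, for cytoplasmic actin, had 10 summits in uninduced MEF and 3 in induced MEF on day 7. Around Etv2 itself 10 summits were called in each of the 3 EB lists from 12 h, 3 to 6 in the floxed EB and 1 to 5 in the MEF lists. The inducible copy cannot be told apart from the endogenous gene.

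The first question was where chromatin opens and closes when Etv2 is induced in fibroblasts. On day 1, fibroblast genes lost accessible positions while a few endothelial genes gained them. Prrx1, a mesenchymal homeobox gene (chromosome 1, 163245119 to 163315145), had 10 summits lost and 0 gained. Runx2, a regulator of the osteoblast lineage, lost 9 and gained 2. Cd34, a surface protein of progenitors and endothelium (chromosome 1, 194938821 to 194961292), gained 4 and lost 1, as did Flt4, the receptor for lymphatic growth factors. The endothelial transcription factor Sox18 gained 2 and lost 0, and Lmo2, a blood and endothelial cofactor, gained 2 and lost 0.

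Across the 48 fibroblast genes on day 1, 39 had more lost than gained summits and 6 the reverse, a median of -2.5 per gene at percentile 0.050 of random lists. With a gene window of 10 kb the percentile was 23.2, and with equal list lengths it was 51.7, so by the median neither setting keeps the list apart. Tied medians can give such middle values, and the mean was not ranked in these settings. The 50 endothelial genes did not stand apart (8 higher and 34 lower, percentile 47.9), and Egfl7, an endothelial secreted factor, lost 6 and gained 0. Of 22 haematopoietic genes 5 were higher and 12 lower (percentile 47.8), with Gata2, a stem cell transcription factor, at 6 lost and 0 gained. Genes of other lineages were also low. The cardiac list lay at percentile 0.22 and the neural list at 0.23, and neither stood apart with equal list lengths (50.3 and 50.2). In all, 10525 summits (21.0% of the day-1 list, 20.7 to 21.4%) were gained and 23340 lost. Only 17.8% of the gained summits were at gene ends, against 31.6% of shared ones. With a score of at least 10 the counts were 2840 and 12103.

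On days 2 and 7, with shorter lists, fibroblast genes had more lost summits. Runx2 lost 20 summits on both days, and the induced lists held 7 and 5 near it. Fosl1, an AP-1 subunit gene of activated fibroblasts, lost 18 on both days, and Zeb2, a mesenchymal repressor, kept 0 of 16 on day 2. Fibroblast genes were lower in 45 of 48 cases on day 2 and in 46 on day 7. Their medians of -6.5 and -8 per gene lay at percentiles 0 and 0.005. With equal list lengths these became 56.6 and 58.1. Endothelial and blood genes lost summits too. Ets1, an ETS factor of endothelium and lymphocytes, lost 14 on each day, Eng, an endothelial co-receptor for TGF-beta, lost 13 and gained 1 on day 2, and Runx1, a regulator of blood stem cells, lost 16 on day 2 and 17 on day 7. The endothelial list stood at percentile 37.8 on day 2 (0.015 by the mean) and 0.395 on day 7, where equal list lengths gave 1.47.

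Totals were 5190 gained and 41396 lost on day 2, and 5262 gained and 49457 lost on day 7, so losses followed list length. Gained and lost counts largely set list length themselves, so this cannot tell lower depth from closing of chromatin. Equal list lengths gave 9262 gained and 9912 lost on day 2, and 9088 and 9723 on day 7. Because all days share the uninduced list, gained regions of different days overlap without any effect. For this overlap, neighbouring summits of all MEF lists, each within 250 bp of the next, were joined into 91100 regions. Of these, 7330 were gained on day 1 and 2895 on day 2, a different base from the gained summits counted above. Of regions gained on day 1, 14.8% were also gained on day 2. Simulated unchanged lists gave 18.4% (17.2 to 19.2%), and independent draws from regions absent from the uninduced list gave 8.05%. Of those gained on day 2, 37.9% were also gained on day 7, against 15.3% (14.04 to 16.6%) simulated and 8.68% independent. Day-1 regions lay slightly above the simulated range on day 7 (12.6% against 11.5%, 10.7 to 12.1%) and in Flk1-positive cells (24.1% against 21.6%, 20.9 to 22.7%), and below it on day 2. The single control list cannot be split, and part of this excess may come from it.

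In the day-7 cells sorted for Flk1, endothelial genes carried summits that the unsorted cells lacked. Cdh5, the endothelial junction cadherin, gained 5 and lost 1 relative to the unsorted day-7 list. Flt1, a receptor for vascular endothelial growth factor, Egfl7, Plvap, a protein of endothelial diaphragms, and Ets1 gained 4 and lost 0 each. Itga2b, an integrin of megakaryocytes and early blood progenitors, gained 5 and lost 0. Fibroblast genes gained as well, with Ccn1, a matrix-associated signalling protein, at 9 gained and 0 lost and the collagen gene Col1a2 at 7 and 0. The sorted list was the longer one, with 16142 summits gained and 4778 lost.

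The haematopoietic list stood apart in this sort (18 of 22 genes higher, percentile 99.4, but 94.4 with equal list lengths and 92.9 by the mean), while the endothelial (36 of 50 higher, percentile 53.8) and fibroblast lists (37 of 48 higher, 49.0) did so only by the mean (99.97 for both). Against uninduced MEF, the Flk1-positive list had 7270 gained and 40101 lost summits. Hey1, a Notch target gene, gained 2 and lost 0, and Hhex, a homeobox gene of early blood and endothelium, gained 2 and lost 0. Endothelial genes were lower in 45 of 50 cases (percentile 21.1) and fibroblast genes in 42 of 48 (percentile 4.22). By the mean, both lie below 2.5, at 0.16 and 0.020, and with a 10 kb window the fibroblast list was at 0.31.

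Kdr (chromosome 5, 75932827 to 75979072) is the gene of the protein used for the sort, so its state in sorted cells is not an independent finding. Uninduced MEF had 4 summits within 50 kb. On day 1 there were 5, of which those at 75922882, at 75927985 and, inside the gene, at 75970409 had no partner in the uninduced list. Day 2 kept 1 summit and unsorted day 7 had 0. The Flk1-positive cells had 3, at 75922863, 75970231 and 75978350. Brg1-knockdown MEF had 0 or 1 summit in each list, and the 1 on day 2 with doxycycline lay at 75922978. In EB the count was 3 uninduced, 8 induced and 7 in induced Flk1-positive cells. Induced and Flk1-positive EB shared positions inside the gene at 75962397 and beyond its end at 76002268 and 76016335.

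**Figure D2:**
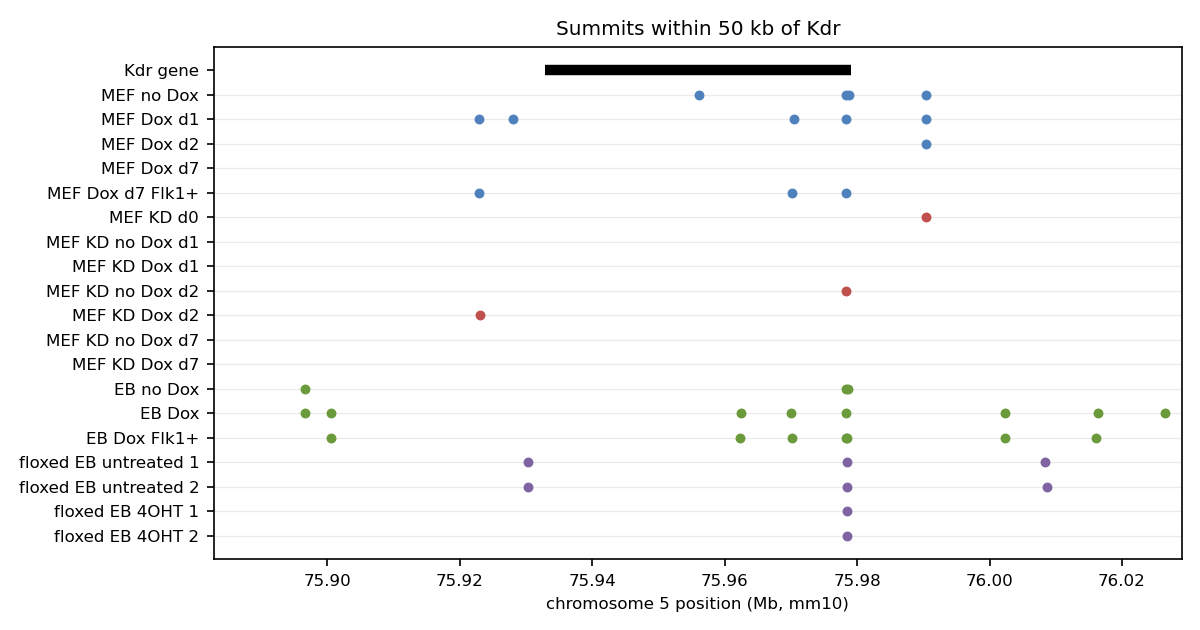
Summits within 50 kb of Kdr by position on chromosome 5 (Mb, mm10), with a row per list and the gene interval as a black bar at the top. A summit near 75922882 appears in induced MEF on day 1, in Flk1-positive MEF and in induced knockdown MEF on day 2, and induced EB have 8 summits against 3 in uninduced EB.

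The second question was what Etv2 does to chromatin when Brg1 is low. Inside the knockdown arm, fibroblast genes lost summits on day 1. Prrx1 lost 7 summits and gained 0, and S100a4, a calcium-binding protein of motile fibroblasts, lost 7 and gained 2. Col1a2 went the other way, with 4 gained and 1 lost. Among endothelial genes Pecam1, a junction adhesion molecule, gained 2 and lost 0, whereas Ets1 and the scavenger receptor gene Stab1 lost 8 each and gained 0. On day 2 Plvap gained 6 and lost 2, Eng gained 4 and lost 2, and Flt1 and Hey1 gained 2 and lost 0, while Sox17, an arterial endothelial transcription factor, lost 5 and gained 0. On day 7 Tek, the angiopoietin receptor gene, gained 3 and lost 0, and Nos3, the endothelial nitric oxide synthase gene, gained 2 and lost 0.

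The fibroblast list stood apart on day 1 only (38 of 48 genes lower, percentile 0.30), and with a 10 kb window it was at 9.745. Equal list lengths gave 1.115. On day 2, 17 fibroblast genes were higher and 17 lower (percentile 54.6), and on day 7 the list was at percentile 50. Endothelial genes were higher in 10 and lower in 29 cases on day 1 (percentile 36.0), 12 and 23 on day 2 (54.5), and 10 and 5 on day 7 (50). Haematopoietic percentiles were 36.5 (1.68 by the mean), 57.0 and 50. Gained and lost summits numbered 7109 and 16359 on day 1, 11451 and 18528 on day 2, and 6127 and 3862 on day 7. With equal list lengths, which make gained and lost nearly balance by construction, the day-7 difference of 2265 in favour of gains was -112.

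Regions gained in MEF without knockdown were looked up in the knockdown lists of the same day. On day 1, 22.0% (21.2 to 22.8%) had a summit in the induced knockdown list and 18.5% in the uninduced one, where shared MEF regions reached 49.1% and 60.6%. On day 2 the values for gained regions were 31.5% and 32.1%, against 81.1% for shared regions in the induced list. On day 7 they were 44.3% and 36.4%, against 48.2%. The day-2 difference between induced and uninduced knockdown was -0.54 points and turned to 0.62 with matching within 100 bp and to 0.41 with equal list lengths. With equal list lengths the day-1 share was 42.4%, and within 100 bp the day-7 share was 25.2%.

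Knockdown and no knockdown lists also differ in how they were processed, and the following values cannot separate these. On day 0 the knockdown list had 8711 summits not in uninduced MEF and lacked 33220 of its summits. Nrp1, a co-receptor of endothelial growth factors, lost 12 and gained 0, and Runx1 lost 11. The endothelial (42 of 50 genes lower, percentile 0.485) and fibroblast lists (43 of 48 lower, percentile 0.21) both stood apart, but not with equal list lengths (49.1 and 42.2). With doxycycline, the knockdown lists held 6045 summits that MEF without knockdown lacked on day 1 and lacked 28314 of theirs. The corresponding counts were 19909 and 7532 on day 2, and 5168 and 9745 on day 7. The sign at endothelial genes followed list length. On day 1, 39 of 50 were lower, with Ets1 at 10 lost and 0 gained, and on day 2, 31 were higher, with Eng at 10 gained and 1 lost.

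In EB, 12 h after Etv2 induction, positions were gained around endothelial genes and around some blood genes. Kdr gained 6 summits and lost 0. Eng (chromosome 2, 32646595 to 32682669) gained 6 and lost 0, Cd34 gained 7 and lost 1, and Adgrf5, an adhesion receptor of endothelium and lung, gained 6 and lost 1. Among blood genes Cbfa2t3, a corepressor of the Tal1 complex, gained 5 and lost 0, Lmo2 gained 4 and lost 0, and Lyl1, a relative of Tal1, gained 9 and lost 4. Some members went the other way. Runx1 lost 9 and gained 0, Gata1, the erythroid regulator, lost 5 and gained 1, and Adgrl4, an endothelial adhesion receptor, lost 6 and gained 1. Msgn1, a gene of presomitic mesoderm, lost 6 and gained 0, and Eomes, a gene of early mesoderm and endoderm, lost 4 and gained 0.

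The endothelial list stood apart in induced EB (27 of 50 genes higher, 15 lower, median 1 per gene, percentile 99.7). With a 10 kb window its percentile was 50.6, and with equal list lengths 93.0. Haematopoietic genes were higher in 11 and lower in 6 of 22 cases (percentile 94.3, and 97.6 by the mean). Pluripotency (10 higher, 12 lower, percentile 62.6), mesoderm (11 and 13, 14.985) and cardiac lists (6 and 10, 16.6) did not stand apart. Within them Klf5, a stem cell factor, lost 5 and gained 0, and the cardiac myosin gene Myh6 gained 6 and lost 0. The whole comparison had 17115 gained and 26015 lost summits. Gained summits were at gene ends in 12.8% of cases (12.3 to 13.3%), against 26.7% of shared ones.

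Sorting induced EB for Flk1 kept part of this pattern in a shorter list, with 10869 gained and 39441 lost summits against uninduced EB. S1pr1, the receptor for sphingosine 1-phosphate on endothelium, gained 4 and lost 0, Kdr and Cd34 gained 5 and lost 1, and Sox7, an early endothelial transcription factor, gained 4 and lost 1. Cdh5 lost 10 and gained 1, and the calcium channel gene Ryr2 of heart muscle lost 10 and gained 0. The mean of gained summits per endothelial gene exceeded that of all 10000 random lists (percentile 100), here matched on the Flk1-positive list alone. The median of gained minus lost, matched on both lists together, did not stand apart (percentile 75.4). These are different measures. Cardiac genes were lower in 16 of 19 cases (percentile 3.86, and 1.32 by the mean) and pluripotency genes in 22 of 25 (4.40), with Nanog, a core pluripotency factor, at 9 lost and 3 gained.

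Against unsorted induced EB, the Flk1-positive list had 7747 gained and 27606 lost summits. Pluripotency genes were lower in 23 of 25 cases (percentile 1.42), with Fgf4 at 9 lost and 1 gained and Pou5f1, for Oct4, at 7 lost and 1 gained. Cardiac genes were lower in 15 of 19 cases (percentile 0.625), with Myh6 at 9 lost and 0 gained. With equal list lengths these were at 40.8 and 46.955. Haematopoietic genes were lower in 15 of 22 cases (percentile 1.20), with Tal1, a master factor of blood formation, at 6 lost and 0 gained. The haematopoietic call ends with the mean (percentile 12.8) and with equal list lengths (39.6). Endothelial genes were lower in 40 of 50 cases (percentile 14.02, and 2.32 by the mean), with Eng at 7 lost and 0 gained.

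**Figure D3:**
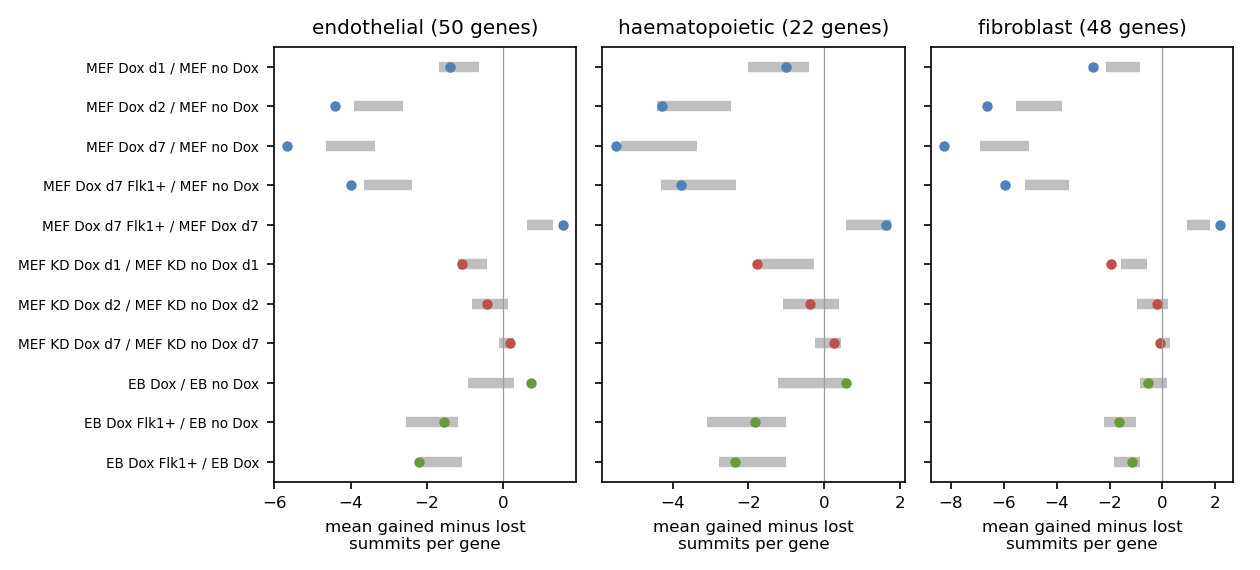
Mean gained minus lost summits per gene (points) for the endothelial, haematopoietic and fibroblast lists in 11 comparisons, with the central 95% of 10000 random lists matched on summit number (grey bars). The endothelial mean of 0.72 in induced EB lies above its grey bar, and the fibroblast mean of -2.62 in MEF on day 1 lies below.

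Lists for other cell types served as a background. In MEF on day 1, gained exceeded lost summits in 3 of 14 endoderm genes, 1 of 12 skeletal muscle genes, 2 of 12 macrophage genes and 5 of 12 epithelial genes, with lost exceeding gained in 6, 9, 7 and 4. For SWI/SNF subunits the numbers were 4 higher and 11 lower of 18, and for housekeeping genes 4 and 14 of 20. In induced EB they were 4 and 5 for endoderm, 4 and 7 for neural, 5 and 3 for skeletal muscle, 4 and 7 for macrophage, 5 and 7 for epithelial, 7 and 5 for SWI/SNF and 8 and 8 for housekeeping genes. Of these, the epithelial list in induced EB stood apart, at percentile 1.95, but not with a 10 kb window (61.2) or by the mean (13.8). Across all 195 pairs, 19 stood apart by the median, of which 5 did so with a 10 kb window and 3 with equal list lengths. By the mean 41 pairs stood apart, among them 14 of these 19. In all, 14 of the 195 pairs stood apart with a 10 kb window and 5 with equal list lengths. Of 200 random lists on simulated data, 2% fell outside the limits by the median and 5.5% by the mean. The 5 pairs at equal list lengths are close to that share by the median.

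Regions gained in induced fibroblasts were then followed into the other systems. This comparison was chosen after the lists had been seen. Among regions called in exactly 1 of the induced and uninduced EB lists, 64.2% (61.9 to 66.4%) of those gained in MEF on day 1 were called with doxycycline, against 55.5% of shared and 47.1% of lost MEF regions. For regions gained in Flk1-positive MEF the values were 68.9% (66.3 to 71.4%), 59.2% and 47.5%. Equal list lengths turned this last difference of 9.65 points to -4.94. For day-2 and day-7 MEF regions the gained values of 57.7% and 56.2% lay within the intervals of shared ones.

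In knockdown MEF the day-1 regions showed the same order, with 58.1% (56.0 to 60.1%) of gained, 26.6% of shared and 18.97% of lost regions called with doxycycline on day 1. Regions of Flk1-positive MEF gave 69.0%, 59.0% and 38.9% in knockdown day 2. In knockdown day 7, the day of these cells, they gave 56.8%, 59.2% and 56.0%, so gained regions did not lie above shared ones there. On day 2 the day-2 regions gave the opposite, 49.0% for gained against 54.6% for shared ones. In the other direction, regions gained in EB were called with doxycycline in 54.5% of MEF day-1 cases (52.2 to 56.7%), against 31.5% of shared and 34.4% of lost EB regions. The gained and shared values were 38.6% and 14.4% in Flk1-positive MEF, 52.5% and 27.8% in knockdown day 1, and 57.9% and 36.4% in knockdown day 2. Lost EB regions also lay above shared ones there, at 19.2%, 33.3% and 38.2%. In knockdown day 7 the order was the other way, with 55.1% and 60.7%.

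**Figure D4:**
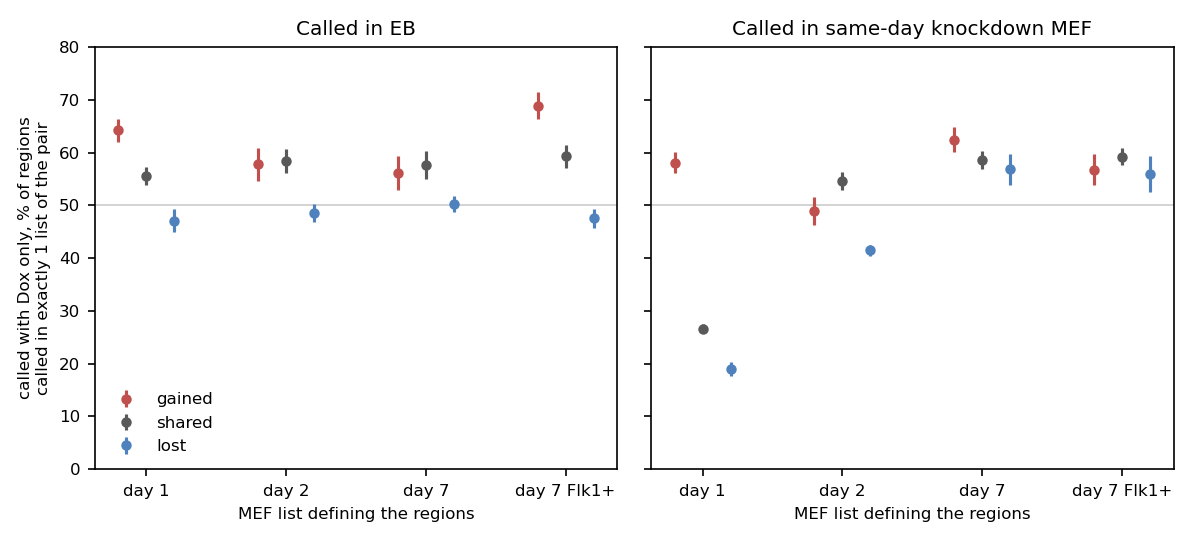
Percent of regions called with doxycycline, among regions called in exactly 1 list of an induced and uninduced pair, for MEF regions gained, shared or lost against uninduced MEF (points with exact 95% intervals), in EB and in knockdown MEF of the same day. Gained day-1 regions reach 64.2% in EB and 58.1% in knockdown, against 55.5% and 26.6% for shared regions.

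The last question was how induced Brg1-floxed EB on day 4 differ with and without 4OHT, which the series text describes as Brg1 knockout. No cells without the floxed gene were given 4OHT, so an effect of the drug itself cannot be told apart from loss of Brg1. Positions missing after 4OHT lay near genes of several lineages. Mesp2, a transcription factor of early mesoderm and somites (chromosome 7, 79810727 to 79813431), had 9 and 8 summits without 4OHT and 2 and 2 with it. Its neighbour Mesp1, a factor of cardiac progenitors, had 9 and 7 against 3 and 3, and Msgn1 7 and 4 against 2 and 1. Aplnr, the apelin receptor gene of early vessels, had 6 and 3 against 0 and 0, and Esrrb, a pluripotency factor, 6 and 5 against 0 and 1. Tnnt2, the cardiac troponin T gene, had 5 and 5 against 1 and 0. Kdr had 3 and 3 against 1 and 1. Cd34 had 2 in each sample, and Nanog had 6 and 5 against 6 and 8.

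A position in both untreated samples and in neither 4OHT sample was counted as lost, and the reverse as gained. By the median of gained minus lost, the fibroblast (percentile 0), endothelial (0.005) and haematopoietic lists (1.655) stood apart, and the cardiac (3.335) and mesoderm lists (4.915) did not. By the mean, the mesoderm (0) and cardiac lists (1.63) stood apart and the haematopoietic list (10.035) did not, while the macrophage list stood apart in the opposite direction (99.74). Lost positions alone, taken as the mean per gene and matched on summits common to both untreated samples, ranked differently. Mesoderm genes lost 1.8 per gene against 0.724 in random lists (percentile 100), where summits near both Mesp1 and Mesp2 count for each gene. They had 38 distinct lost summits against 21 to 36 in draws matched on score and gene ends, and 32 against 19 to 33 without these 2 genes. Losses were also high for fibroblast genes (0.917 against 0.382, percentile 100), cardiac genes (1.05 against 0.539, 99.8) and skeletal muscle genes (0.75 against 0.318, 99.2). Endothelial genes lost 0.72 against 0.478 (96.8) and macrophage genes 0.0833 against 0.40015 (2.69). The percentile of lost positions was 79.0 for haematopoietic, 84.4 for pluripotency, 93.3 for endoderm, 39.5 for neural, 18.8 for epithelial, 33.6 for SWI/SNF and 31.4 for housekeeping genes. The matched draws, which count each summit once, left fibroblast genes above their range (44 against 23 to 38). Cardiac genes (18 against 11 to 21), skeletal muscle genes (8 against 4 to 11) and endothelial genes (36 against 26 to 43) lay inside theirs. In total 4971 regions were in both untreated and neither 4OHT sample, and 1111 the reverse, while the other 4 ways to pair the samples gave 327 to 1097. The count of 1111 is thus close to that of a mixed pair, the first untreated with the second 4OHT sample (1097). Both untreated lists were also the longer ones (31436 and 23823 summits against 17946 and 20229), and list length alone can raise the count of 4971.

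Untreated samples held 27630 ± 5383 summits (SD, n = 2) and 4OHT samples 19088 ± 1614 (SD, n = 2), a difference of -8542 with p = 0.333 in the exact two-sided permutation test, the smallest p that 2 against 2 samples allow. Without the first untreated sample the difference was -4736. The gene-end share was 42.0 ± 6.15% without and 53.5 ± 2.65% with 4OHT. At an equal 17946 highest-scoring summits per sample it was 55.3% and 55.5%. Averaged over pairs, summits matched within a group more often than between groups, by 9.74 percentage points, and by 5.02 at the least when a 4OHT sample was left out. A single pair went the other way, as the second 4OHT sample matched the first untreated sample in 77.1% of its summits and its own partner in 73.6%.

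**Figure D5:**
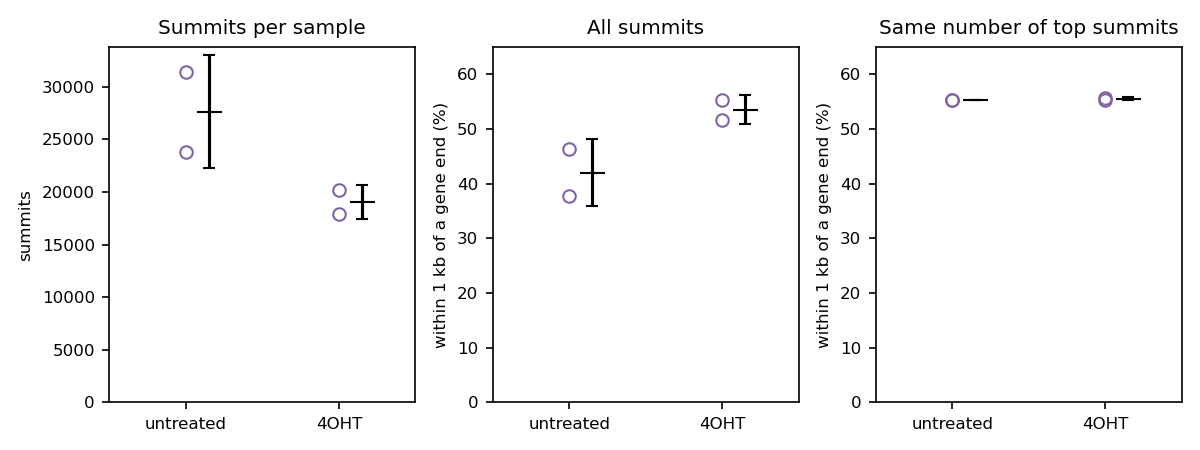
Summits per sample (left), percent of summits within 1 kb of a gene end (middle) and the same percent among the 17946 highest-scoring summits (right) for 2 untreated and 2 4OHT-treated floxed EB samples, with circles for samples and bars for mean ± SD. The gene-end share of 42.0% against 53.5% becomes 55.3% against 55.5% at equal numbers.

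The highest-scoring gained and lost summits mostly sat at places called in many lists. On day 1 in MEF the top gained summit lay at chromosome 1 position 24614624, 26702 bp from Col19a1, its nearest gene. It had a summit within 250 bp in 12 of the 19 lists. The top lost one, at chromosome 15 position 91908214 and 46779 bp from Smgc, had one in 13. The gained summit nearest Col19a1 lies in a 10 kb bin where all 15 pooled lists have a summit scoring at least 200. The next gained one, in Myo3a, a myosin gene of hair cells, lies at the edge of another. A lost EB summit at chromosome 9 position 24542096, 14951 bp from Dpy19l2, a sperm head protein gene, was in 1 list. In the floxed EB the top gained summit lay 3298 bp from Tcstv3, a gene of the early embryo. The top lost one lay 24112 bp from Rpp21, a ribonuclease P subunit.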

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

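None of the following values carries a test of the conditions, and all were picked out after the lists had been seen.

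With Brg1 knocked down, doxycycline went with a shorter list on days 1 and 2 and a longer one on day 7. The induced minus uninduced list length was -8753, -6721 and 2456 summits. Fibroblast genes did not follow list length throughout, with 38 of 48 lower on day 1, 17 higher and 17 lower on day 2, and 5 higher and 8 lower on day 7. With equal list lengths the day-7 gained minus lost count was -112. Equal lengths make gained and lost nearly balance by construction, so this value cannot decide the direction. The difference between days is untested, and there is 1 list per condition.

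Endothelial genes had a mean of 0.72 gained minus lost summits in EB and -1.38 in MEF on day 1, and haematopoietic genes 0.591 and -1. Lmo2 gained in both, 4 in EB and 2 in MEF on day 1. The difference between the cell types is untested, and the 2 systems differ in list length and in time after induction.

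Chromosome Y was left out except in the alternative with every chromosome. The induced and uninduced lists held 74 and 39 summits there in knockdown MEF on day 1, 69 and 54 on day 2, 96 and 77 on day 7, and 291 and 281 in EB. These pairs were picked because the induced count was higher. The other induced lists held fewer than their control. MEF without knockdown had 137, 133 and 137 on days 1, 2 and 7 and 126 in Flk1-positive cells, against 139 uninduced. Flk1-positive EB had 253 against 281. How the reads at its repeats were placed is not recorded in the labels.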

How the results depend on the processing

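Each count and share was computed again under the alternatives, and the mean in place of the median was chosen after the results were seen. The direction of gained minus lost kept its sign in all but 1 of the compared settings. That difference follows the difference in list length, so its sign mostly shows which list is longer. Where a value moved, the cause was not tested.

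Matching within 100 bp breaks up pairs of summits, and matching within 500 bp joins more of them. Gained summits in MEF on day 1 went to 18557 and 6994, on day 2 to 10333 and 2954, and on day 7 to 9096 and 3327. In Flk1-positive MEF the narrow window gave 12699. Against unsorted day 7, lost summits became 8871 and 2933. In knockdown MEF, gained summits on day 1 became 13311 and 4131, gained summits on day 2 became 18466 with the narrow window, and lost summits on day 7 became 6440. Induced EB gained 28102 with the narrow window. Flk1-positive EB gained 21034 and 6881 against uninduced EB, and 17946 and 4267 against unsorted induced EB.

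A score of at least 10 leaves the strong summits. Gained and lost were then 2840 and 12103 in MEF on day 1, 1132 and 25222 on day 2, 1260 and 28670 on day 7, and 1793 and 22441 in Flk1-positive MEF. Flk1-positive against unsorted day 7 gave 7899 and 1134. Knockdown MEF gave 1254 and 7754 on day 1, 3095 and 5711 on day 2, and 1418 and 699 on day 7. Induced EB gave 6999 and 12106. Flk1-positive EB gave 2738 and 23374 against uninduced EB, and 1553 and 17223 against unsorted induced EB.

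Taking the same number of highest-scoring summits removes differences in list length. Lost summits in MEF on day 1 were then 14191. Gained and lost were 9262 and 9912 on day 2, 9088 and 9723 on day 7, and 11941 and 12535 in Flk1-positive MEF. Flk1-positive against unsorted day 7 gained 7517. Knockdown MEF on day 1 lost 9088. Flk1-positive EB lost 16881 against uninduced EB, and gained 11875 and lost 12383 against unsorted induced EB. Equal lengths also make gained and lost counts nearly balance by construction. In knockdown MEF on day 7 their difference was 2265 in the main setting and -112 here, which does not show a change of direction.

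The share of MEF-gained regions found in induced knockdown MEF of the same day was 16.5%, 24.7% and 25.2% on days 1, 2 and 7 with the narrow window. With the wide window it was 34.2% on day 2 and 59.9% on day 7. A score of at least 10 gave 17.99%, 27.1% and 58.5%. Equal list lengths gave 42.4% on day 1 and 55.9% on day 7. On day 2 the induced minus uninduced share, -0.539 points in the main setting, turned to 0.619 with the narrow window and to 0.410 with equal list lengths.

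The doxycycline-only share of gained minus shared regions was 8.70 points for MEF day-1 regions in EB, and 3.36 and 17.2 with the narrow and wide windows. For day-2 regions in EB it went from -0.619 to 3.09 with the wide window and to -7.95 with equal list lengths. For day-7 regions in EB it was -1.44 in the main setting, -4.73 with the narrow window, 6.59 with a score of at least 10 and -8.81 with equal list lengths. For regions of Flk1-positive MEF in EB, 9.65 points became 3.06 and 15.04 with the narrow and wide windows and 13.1 with a score of at least 10, and turned to -4.94 with equal list lengths.

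In knockdown MEF, day-1 regions on day 1 had 31.5 points, and 18.7, 37.6 and 39.2 with the narrow window, the wide window and a score of at least 10. Day-2 regions on day 2 went from -5.64 to -2.57 with the narrow window and to -24.9 with a score of at least 10. Day-7 regions on day 7 had 3.78 points, and 9.09 with the wide window, 8.93 with a score of at least 10 and 7.996 with equal list lengths. Regions of Flk1-positive MEF on day 2 went from 10.0 points to 5.13 and 15.7 with the 2 windows and to 6.81 with equal list lengths.

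Gene-list calls by the median depended on window and list length, although middle percentiles there may only reflect tied medians. With a gene window of 10 kb the fibroblast list was at percentile 23.2 in MEF on day 1, 0.31 in Flk1-positive MEF and 9.745 in knockdown MEF on day 1. The endothelial list was at 0.115 in MEF on day 2 and at 50.6 in induced EB. With equal list lengths the fibroblast list was at 51.7, 56.6 and 58.1 in MEF on days 1, 2 and 7. The endothelial list in induced EB was then at 92.955, and the haematopoietic list in Flk1-positive against unsorted EB at 39.6. With the mean, the endothelial list was at 0.015 in MEF on day 2, at 0.16 in Flk1-positive MEF and at 2.32 in Flk1-positive against unsorted EB. The fibroblast list was at 0.020 in Flk1-positive MEF. The haematopoietic list was at 97.6 in induced EB and at 12.8 in Flk1-positive against unsorted EB. Of the 19 pairs that stood apart, 5 did so with the 10 kb window and 3 with equal list lengths. The latter were the endothelial list in MEF on day 7 (1.47), the fibroblast list in knockdown MEF on day 1 (1.115) and the epithelial list in induced EB (0.29). With equal list lengths 5 of the 195 pairs stood apart in all. That is close to the 2% of random lists outside the limits by the median on simulated data.

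For the floxed EB, leaving out a sample gave differences in summit number from -12348.5 to -4735.5, the latter without the first untreated sample. The within minus between agreement ran from 5.02 to 14.9 points. With the replicate block the difference was -8542 and the two-sided exact sign-flip p was 0.5, from paired differences of -13490 and -3594. With a score of at least 10 the difference was -1172.5 with p = 0.667 in the exact two-sided permutation test.

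The motif alternatives (a 50 bp window around the summit, summits away from gene ends only, and the longer ETS motif) were not run, since the motif results need the genome sequence. List length limits every count of gained and lost summits and most gene-list calls. It was the only stand-in for depth here and need not follow depth.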

Other observations

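The explanations for the length of day-7 lists by depth and for gene-end share by list length were tested after the result had been seen, as was the count without Mesp1 and Mesp2, while the other predictions were written before their test was run, with related values known.

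Knockdown MEF kept without doxycycline also had different accessible positions by day 7. Of 48 fibroblast genes 25 were higher and 17 lower on day 1 against day 0, 23 and 11 on day 2, and 2 and 44 on day 7. Gained and lost summits numbered 9921 and 10690 on day 1, 17345 and 9177 on day 2, and 4507 and 30351 on day 7. The day-7 list is the shortest, these comparisons were not made at equal list lengths, and the difference between days is untested.

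The day-7 MEF lists are short with and without doxycycline, and the uninduced knockdown list of day 7 is the shortest. Depth alone would leave the strongest regions of day 0, but only 59.7% of its summits matched a day-0 summit, against 95.9% of as many highest-scoring day-1 summits. Its gene-end share of 29.1% also lay below the 58.6% of as many highest-scoring day-0 summits. Day-7-only and day-1-only regions are summits of the uninduced knockdown list of that day with no partner in the day-0 list. Background positions called in any cell type stay open. Day-7-only regions were called in an EB list 7.12 points more often than day-1-only regions (44.6% against 37.5%) but in uninduced MEF less often (30.4% against 42.9%). Of day-7-only regions 47.2% were called in induced MEF without knockdown on day 7, against 10.4% of day-1-only regions. In induced MEF without knockdown on day 2 the values were 41.8% and 15.6%, so this overlap was not particular to day 7. Time in culture stays open because no uninduced day-7 list without knockdown was used here.

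After 4OHT the floxed EB lists hold a larger share of gene-end summits and fewer summits at Mesp1, Mesp2 and Msgn1. The gene-end share is in line with list length, since the difference of 11.5 points was 0.220 at equal numbers of summits. Uniform loss of weak summits is argued against by mesoderm genes, which lost 38 summits where matched draws gave 28.5 (21 to 36), a ratio of 1.34. Without Mesp1 and Mesp2, which share their neighbourhood, 32 were lost against 25.6 (19 to 33), a ratio of 1.25 just inside the range. The mesoderm count thus leaves its range only with that locus. Outside their ranges without it, fibroblast genes lost 44 against 23 to 38, epithelial genes 4 against 7 to 16, neural genes 9 against 10 to 21 and macrophage genes 1 against 2 to 8. The lists not named in this paragraph lay inside their ranges. The draws treat neighbouring summits as independent, and the exact two-sided permutation test with 2 samples per group allows no p below 0.333. An effect of Brg1 therefore stays open, and it cannot be told apart from an effect of 4OHT itself.

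Regions gained in MEF on day 1 and in Flk1-positive MEF are called with doxycycline in EB more often than shared regions, whereas day-2 regions are not (57.7% against 58.4%). Weak score and distance from gene ends are argued against in the 3 pairs where shared regions were matched on both, which reached 53.6% for day-1 regions in EB (against 64.2%), and for regions of Flk1-positive MEF 57.5% in EB (against 68.9%) and 59.3% in knockdown day 2 (against 69.0%). No matching was done for day-1 regions in knockdown day 1, where the difference was largest. Nor was it done for regions of Flk1-positive MEF in knockdown day 7, where gained ones (56.8%) lay below shared ones (59.2%). Equal list lengths argue the other way for Flk1-positive regions in EB, where the difference from shared regions was -4.94 points. Whether Etv2 opens the same regions in both systems stays open with 1 list per condition, and the ETS motif that could separate direct from indirect regions was not analysed here.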
